A study of Mus musculus with 6 samples.

How the data were processed

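Small RNA was sequenced from the sensorimotor cortex of adult (postnatal day 90) male C57BL/6J mice. The 6 libraries fall into 2 groups of 3, which were assigned from the treatment stated in the labels: control surgery, and complete transection of the cervical spinal cord (SCI), both sampled 7 days after surgery. Per the labels' protocols, the samples were collected individually, RNA was extracted with the mirVana kit, libraries were made with HD adapters, whose ends carry degenerate bases that reduce ligation bias, and single-end reads were sequenced. The labels name the animals' samples as separate but give no batch or date, so none was used.

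The authors deposited, for each library, a table of distinct read sequences with the raw read count of each, per the file headers. The sequences were 17 to 34 nt long and each was listed once per library. The adapter trimmer, aligner and read filters were not given in the sources used here. The genome build GRCm38 is named in the submitters' processing notes. Total counts per library were 22937179, 10585062 and 24480988 in control 1, 2 and 3, and 14628518, 23408028 and 19918863 in SCI 1, 2 and 3. A share of counts in 1 library was given a 95% Wilson interval. The reads carry no molecular identifiers, so intervals cover counting error only.

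Every distinct read was matched here, on the sense strand and without mismatch, to the transcripts of GENCODE release M21, which is built on GRCm38. Each read was given 1 class, with miRNA hairpins first. This annotation holds hairpins without mature miRNA coordinates and holds no nuclear tRNA genes, and the genome sequence was not used here, so reads of nuclear tRNAs, piRNAs or intergenic RNAs stand among the reads without a match. Reads of 18 to 26 nt were counted per hairpin arm by the side of the hairpin midpoint on which the read's own midpoint fell, over 1174 named hairpins. Arms with the same most abundant read, or sharing at least 50% of the reads of the smaller arm, were merged under a joint name, and reads still found in several arms were left out (0.1% to 0.153% of reads per library). In 2 alternatives the most abundant read of each arm stood in for an annotated mature sequence. Reads with bases added at the 3' end did not match, and reads carrying 1 to 3 such bases made up 9.11% to 10.2% of each library. Between 72.9% and 78.9% of the reads entered the miRNA counts. Chi-square values of every pair of libraries, over 441 miRNAs, lay far above sampling noise (174.5 to 1592.7 per degree of freedom). No library was thus a copy or a repeat sequencing of another. The values cannot tell animals apart, and all 6 libraries were counted as separate samples because the labels give them as such.

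Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, on all 6 libraries without covariates. Benjamini-Hochberg adjusted p under 0.05 counted as passed. Levels are CPM, relative to all reads counted in miRNA arms and scaled by TMM. For single sequences and RNA classes they are shares of all reads in the library. The 15 miRNA lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01 and, beside it, with an estimated correlation and with fry. Camera compares a list with all other miRNAs, whereas fry tests whether its members move one way on balance. The 3' over 5' arm ratio of each hairpin with a mean of at least 10 counts in both arms was tested with limma on log2 ratios with a pseudocount of 0.5. Single sequences with a total of at least 10 counts entered the same edgeR procedure. RNA class shares were compared with two-sided exact permutation tests of the difference of group means, for which 3 libraries against 3 allow no p below 0.1. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

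The groups, tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. No source was recorded for the lists or for the fixed set of miRNAs. Whether they draw on earlier results from these samples is thus not known. The rule takes up to 10 miRNAs per direction with the largest change among those that pass. Where fewer than 10 pass it takes the 5 of smallest unadjusted p with a mean of at least 10 CPM in 1 group. It always adds a fixed set (miR-7b-3p, miR-7a-5p, miR-7b-5p, miR-21a-5p, miR-124-3p, miR-132-3p, miR-155-5p, miR-146a-5p, miR-223-3p, miR-451a, miR-219a-2-3p, miR-126a-3p, miR-9-5p and miR-133b-3p), the 5 most abundant miRNAs and up to 4 members of each list with the smallest unadjusted p. For sequences it takes the 3 of smallest p in each direction. Reads of miR-133a-3p and miR-133b-3p were merged into 1 count. Positions are those of the hairpin gene in the annotation.

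The alternatives were DESeq2 size factors, total count and upper quartile scaling, DESeq2 1.42.0 and limma-voom as tests, other count filters, the replicate number as a block, leaving out each library in turn, narrower and wider read matching and, for class shares, other read lengths and distinct sequences counted once. Counting tailed reads, sharing out reads of several arms and leaving out arms found in 10 or more other genes were added after seeing the data. The procedure was tested on simulated counts drawn from the real means and library sizes. Of 97 miRNAs changed 2-fold 81.4% were called, of 97 changed 4-fold 100%, and of 485 left unchanged beside them 1.03%, with 690 miRNAs tested. Both sets were changed together, and an adjusted p passes more easily when many miRNAs change. The shares called thus do not tell how many changes the test would miss if only a few miRNAs changed. Of 171 sequences changed 4-fold, 21.6% were called among 31242, and of 96 hairpins whose arm ratio was changed 4-fold, 97.9% were called. Sequences without a match to the annotation are given by length and level only.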

Results

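Small RNA libraries were compared between the sensorimotor cortex of mice whose cervical spinal cord had been cut through 7 days earlier (SCI) and that of mice whose cord had only been laid bare (control). The cortex holds the cell bodies of neurons whose axons descend into the cord, so the comparison asks which small RNAs differ at a distance from the lesion. There were 3 libraries per group, with 10585062 to 24480988 reads in the control libraries and 14628518 to 23408028 in the SCI libraries. Of 1422 miRNA arms with at least 1 read, 690 were abundant enough to be tested. Levels are given as TMM-scaled CPM (counts relative to the library's total), mean ± SD of n = 3 libraries per group, and fold changes as log2 of SCI over control ± SE. For edgeR the SE was derived from the test, as the size of the fold change divided by the square root of its F statistic. It reflects the spread as the test estimates it and can be narrower than the spread of the libraries.

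Most reads in both groups came from miRNA hairpins, which took 78.9% ± 0.459 of the control reads and 75.2% ± 2.99 of the SCI reads. Mitochondrial tRNA fragments took 0.529% ± 0.141 in control and 0.849% ± 0.146 in SCI libraries, and all 3 SCI libraries lay above all control libraries. Reads without a match to the annotated transcripts took 17.1% ± 0.475 and 20.1% ± 2.14, again with all SCI libraries above all controls. SCI 1, at 17.66%, lay only just above control 1, at 17.48%. miRNA reads with 1 to 3 bases added at the 3' end, which did not match, took 10.2% of SCI 1. They took 9.26% to 9.78% of the control libraries, so the place of SCI 1 above the controls may rest on them. Ribosomal RNA fragments took 0.977% ± 0.163 and 1.15% ± 0.171, and fragments of mRNA or long noncoding RNA 1.23% ± 0.104 and 1.57% ± 0.471. Long reads of 30 to 34 nt took 0.584%, 3.66% and 2.31% in SCI 1, 2 and 3, against 1.33%, 0.611% and 0.543% in control 1, 2 and 3. Exact two-sided permutation tests gave p = 0.1 for mitochondrial tRNA and for unmatched reads, which is the smallest p that 3 libraries against 3 can give, 0.2 for miRNA hairpins and rRNA, 0.3 for long reads and 0.4 for mRNA. The difference of means for mRNA was 0.341 points, but 0.112 without SCI 2 and 0.583 without SCI 1, for long reads 1.36 points, but 0.622 and 2.16, and for rRNA 0.176 points, but 0.1015 without control 1, 0.109 without SCI 2 and 0.272 without SCI 1. The 95% Wilson intervals of these shares were at most 0.0492 percentage points wide. With each distinct sequence counted once, the difference in share turned to -0.152 points for mitochondrial tRNA, -0.101 for rRNA and -0.529 for mRNA.

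**Figure D1:**
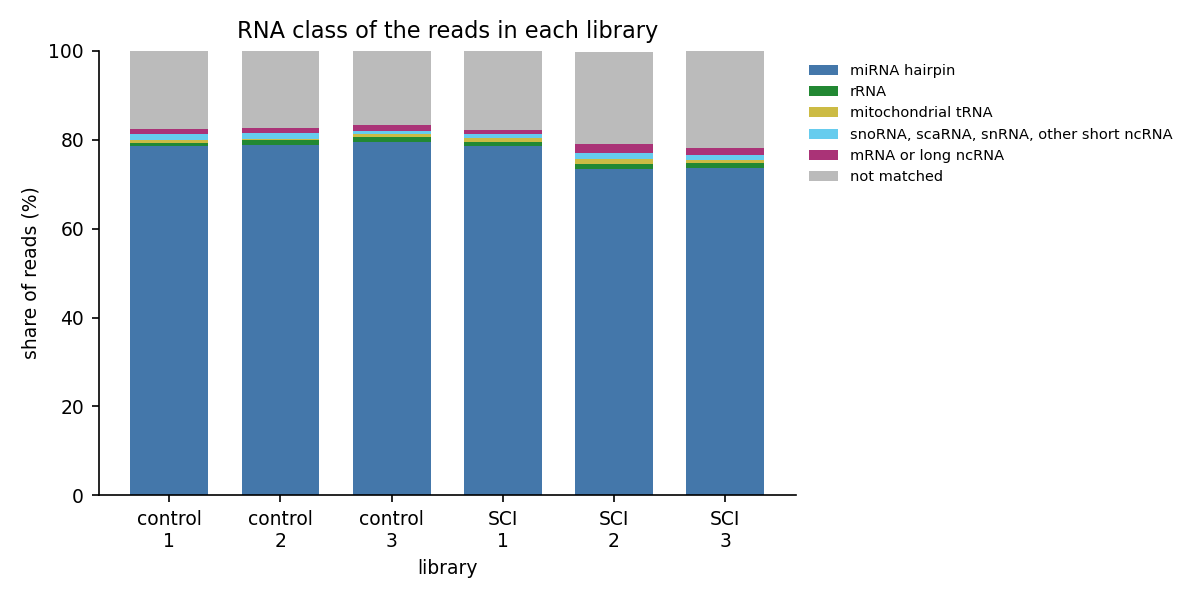
Share of reads (%) in each RNA class for the 6 libraries, as stacked bars from 0. miRNA hairpins take 73.3% to 79.4% of every library, and reads without a match take 20.9% and 21.7% in SCI 2 and SCI 3 against 16.5% to 17.7% in the others. The small remainder to the full height is predicted miRNA-type hairpins.

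miR-29a-3p, miR-128-3p, miR-9-5p, miR-26a-5p and miR-9-3p were the 5 most abundant miRNAs over the 6 libraries, and miR-29a-3p stood at 93424 ± 19693 CPM in control and 75168 ± 6584 in SCI (-0.31, and -0.13 without control 1). Among miRNAs with the smallest p, miR-143-3p, which is abundant in vascular smooth muscle, stood at 4370 ± 353 CPM in control and 3074 ± 148 in SCI (-0.51 ± 0.11). miR-181b-5p stood at 5756 ± 243 and 4344 ± 187 (-0.41 ± 0.11), miR-543-3p at 705 ± 84.3 and 441 ± 92.1 (-0.67 ± 0.18), and miR-9-5p, a regulator of neural progenitors, at 80166 ± 6640 and 63415 ± 2319 (-0.34 ± 0.10). miR-132-3p, which neuronal activity induces through CREB, stood at 24440 ± 1324 and 18014 ± 2495 (-0.44 ± 0.13). Each of these was lower in all 3 SCI libraries than in any control library.

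The miRNAs of smallest p in the other direction were minor arms or weakly expressed. miR-181b-1-3p, the arm opposite miR-181b-5p in 1 of its hairpins, stood at 5.61 ± 1.51 CPM in control and 14.96 ± 4.41 in SCI (1.42 ± 0.29). miR-345-3p stood at 14.6 ± 2.61 and 27.6 ± 2.36 (0.91 ± 0.19), miR-3072-3p at 17.7 ± 3.88 and 35.97 ± 8.005 (1.02 ± 0.23), and miR-187-3p at 30.5 ± 2.16 and 47.3 ± 4.70 (0.63 ± 0.16). The joint count of miR-466f, miR-466i, miR-466k and miR-466q, whose most abundant read is a TG repeat found in 1658 other genes, stood at 5.96 ± 1.74 and 16.96 ± 7.18 (1.496 ± 0.35). All 5 were higher in every SCI library than in any control library.

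None of these single differences passed. The edgeR quasi-likelihood test passed 0 of 690 miRNAs (smallest adjusted p 0.116), with 97 at an unadjusted p under 0.05, of which 56 were higher and 41 lower. limma-voom passed 0, with 93 at an unadjusted p under 0.05, and DESeq2 passed 12, 10 higher and 2 lower, with 88. Those 12 include miR-143-3p, miR-543-3p, miR-181b-1-3p, miR-345-3p, miR-3072-3p, miR-187-3p, miR-1197-3p and the joint count of miR-466f, miR-466i, miR-466k and miR-466q. The groups did not overlap for 140 miRNAs (63 higher, 77 lower in SCI), 20.3% of those tested, where chance gives 10%. The edgeR count was 2 without SCI 1 (miR-1954/5098-3p, singled out after its values were seen, and the joint count with miR-466f) and 7 without SCI 2, and 30 of 1422 without the filter on low counts, and the number at an unadjusted p under 0.05 was 48 without SCI 3. Control 1 stood apart on the first principal component (-8.01 against -0.26 to 4.07 for the other libraries, 42.9% of the variance), and without it edgeR passed 0, with 103 at an unadjusted p under 0.05. Scaling by total count moved the log2 fold changes by a median of 0.12. Leaving out the filter on low counts moved them by a median of only -0.0077. Calls made without that filter, here and below, thus rest on a changed estimate of the spread and not on larger differences.

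**Figure D2:**
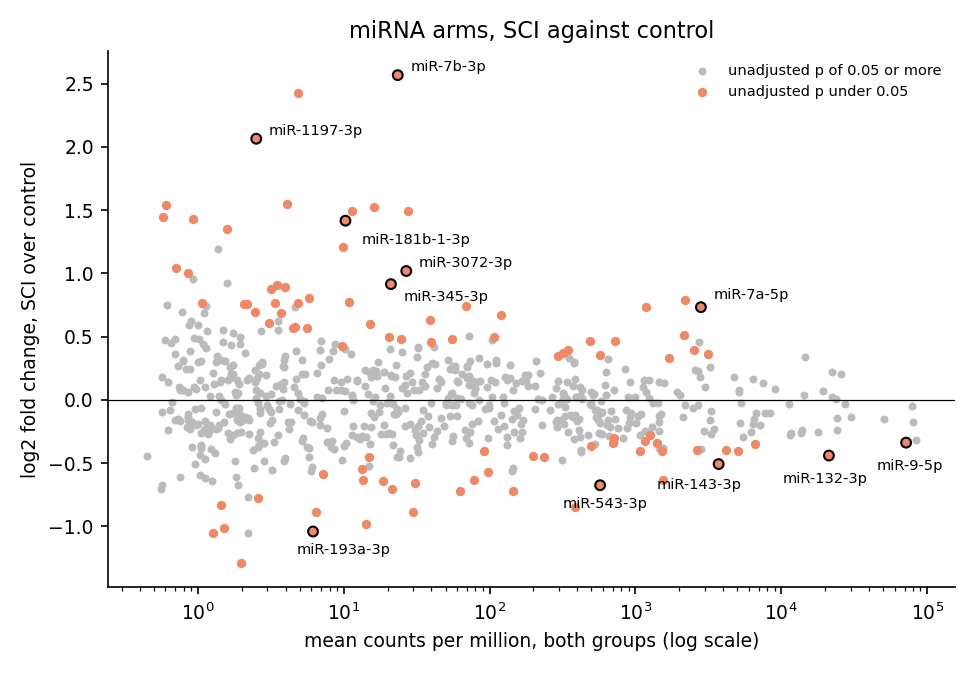
log2 fold change of SCI over control for the 690 tested miRNA arms against their mean CPM on a log scale. Orange points are the 97 arms with an unadjusted p under 0.05, of which none passed the adjusted test, and circled points are named examples, from miR-7b-3p at 2.57 to miR-193a-3p at -1.04.

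The miR-7 family, enriched in neurons and neuroendocrine cells, had all 5 of its members higher in SCI under each of the 4 scalings tried. miR-7b-3p showed the largest difference, from 6.70 ± 0.960 CPM in control to 40.3 ± 40.9 in SCI (2.57 ± 0.71, and 1.37 without SCI 1). Its level was 86.0 in SCI 1, 7.25 in SCI 2 and 27.5 in SCI 3, against 5.60 to 7.39 in the control libraries. miR-7a-5p stood at 2115 ± 275 and 3514 ± 1215 CPM (0.73 ± 0.24) and miR-7b-5p at 895 ± 86.2 and 1486 ± 520 (0.73 ± 0.24). For both, SCI 1 and SCI 3 lay above every control library and SCI 2 lay within the control range. miR-7a-1-3p stood at 278 ± 27.1 and 359 ± 26.8 (0.37 ± 0.14), with all SCI libraries above all controls, and miR-7a-2-3p differed by 0.39 ± 0.32. The edgeR adjusted p over all miRNAs was 0.256 for miR-7b-3p, miR-7a-5p and miR-7b-5p, and all 3 were among the 7 miRNAs that passed in edgeR without SCI 2.

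The miR-7 genes lie on 3 chromosomes in GRCm38. The Mir7b hairpin (ENSMUSG00000065491.1), a noncoding miRNA gene, spans chromosome 17, 56242988 to 56243098, on the plus strand, and its 3p arm was read mainly as CAACAAGTCACAGCCAGCCTCA. That read made up 83.1%, 80% and 84.4% of the miR-7b-3p reads in control 1, 2 and 3, and 49.1% (95% Wilson interval 46.0% to 52.2%), 82.8% and 74.1% in SCI 1, 2 and 3. The miR-7a-5p sequence TGGAAGACTAGTGATTTTGTTGTT lies in Mir7-1 (chromosome 13, 58392779 to 58392886, minus strand) and in Mir7-2 (chromosome 7, 78888277 to 78888373, plus strand). miR-7b-5p was read mainly as TGGAAGACTTGTGATTTTGTTGTT, and no reads of these arms were shared with other hairpins.

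As a list, the miR-7 family was the 1 of 15 that passed camera with the preset correlation (median log2 fold change 0.73, adjusted p = 0.0305). With an estimated correlation it did not pass (p = 0.140, adjusted p = 0.782), and fry gave p = 0.0909 (adjusted p = 0.488) by its rotation test in limma. Adjusted over the list alone, 4 of the 5 members passed in edgeR (miR-7b-3p, miR-7a-5p and miR-7b-5p at 0.0239, miR-7a-1-3p at 0.0332), and 0 passed over all miRNAs tested. Without the filter on low counts miR-7b-3p, miR-7a-5p and miR-7b-5p passed in edgeR over all miRNAs and over the list alone. The edgeR adjusted p of miR-7b-3p was then 2.2e-21, although SCI 2 lay within the control range, so it overstates the difference between the groups. The camera adjusted p was 0.0668 with total count scaling, 0.188 without control 1, 0.187 without control 3 and 0.245 without SCI 1. Adjusted over the list alone, 0 members passed without control 3 or without SCI 1, and 1, miR-7b-3p, without SCI 3.

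**Figure D3:**
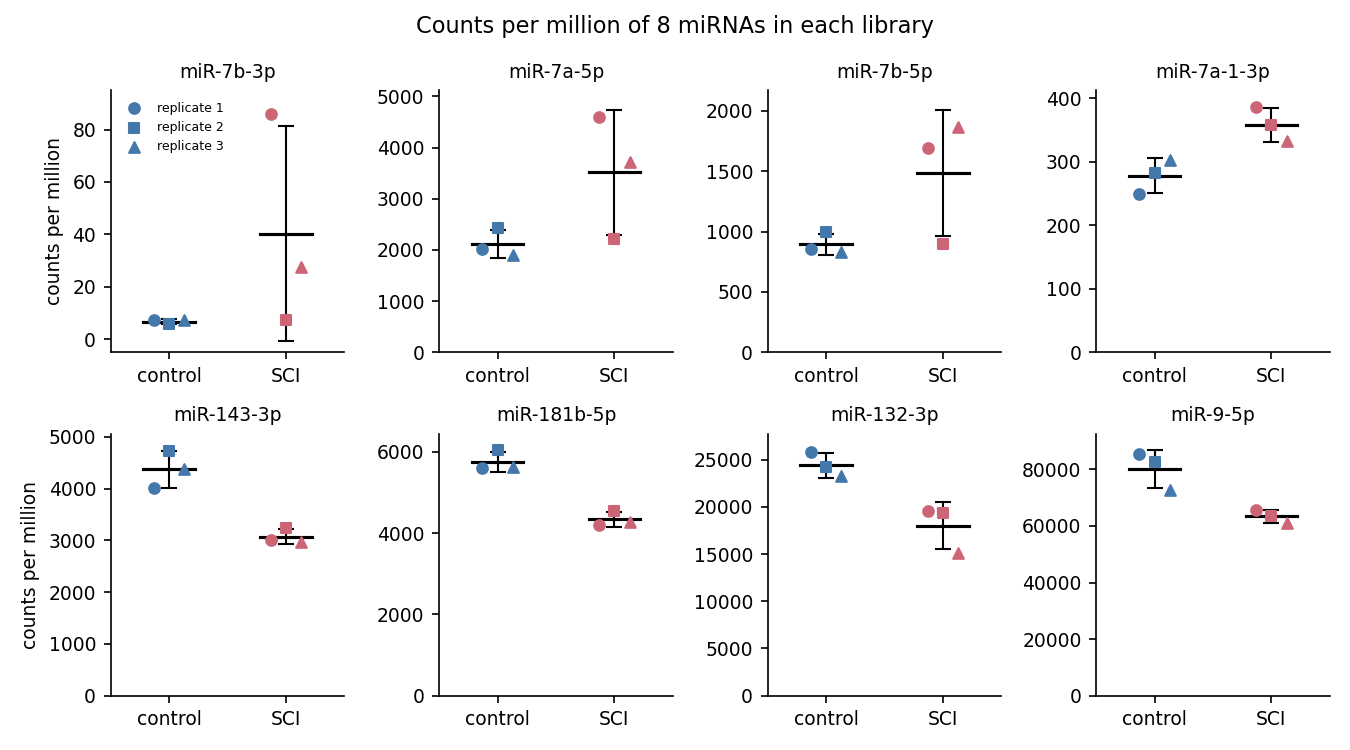
CPM of 8 miRNAs in each library, with the marker shape giving the replicate number and black bars the mean ± SD of 3 libraries. miR-7b-3p stands at 86.0 in SCI 1 and 7.25 in SCI 2, while miR-143-3p, miR-181b-5p, miR-132-3p and miR-9-5p are lower in every SCI library than in any control library.

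Lists of glial and vascular miRNAs had more members lower than higher in SCI, as did the neuronal lists given further on. Over all 690 tested miRNAs the median log2 fold change was -0.02. Of 14 astrocyte-associated miRNAs 10 were lower and 4 higher (median -0.26), and adjusted over the list alone, 3 fell: miR-143-3p, miR-181b-5p and miR-193a-3p (-1.04 ± 0.32, adjusted p = 0.0417 in edgeR). miR-32-5p differed by -0.57 ± 0.21 (-0.35 without control 1) and miR-449a-5p by 0.57 ± 0.21 without passing. Of 14 endothelial and mural cell miRNAs 9 were lower and 5 higher (median -0.23). Adjusted over the list alone 1 fell, miR-143-3p (edgeR adjusted p = 0.0209), which stands in both lists, while miR-145a-5p, co-transcribed with miR-143, differed by -0.28 ± 0.13, miR-143-5p by -0.53 ± 0.30 (-0.23 without control 1) and miR-126a-3p, an endothelial miRNA, by -0.27 ± 0.16 (-0.18 without control 3). Of 8 oligodendrocyte-enriched miRNAs 6 were lower and 2 higher (median -0.15). With total count scaling the medians of the astrocyte, endothelial and oligodendrocyte lists were -0.14, -0.12 and -0.04, still with more members lower than higher. miR-219a-5p, needed for oligodendrocyte maturation, stood at 494 ± 244 CPM in control and 274 ± 32.8 in SCI (-0.85 ± 0.31), with 759 in control 1 and -0.40 without it, while miR-338-3p differed by -0.29 ± 0.15 (-0.14 without control 3) and miR-219a-2-3p by -0.18 ± 0.14 (-0.30 without control 1, -0.11 without control 2). Over all miRNAs tested, 0 members of these lists passed in edgeR and 1, miR-143-3p, in DESeq2, with unadjusted p under 0.05 for miR-219a-5p, miR-27a-3p and the 5 astrocyte-associated members named here. Without the filter on low counts miR-143-3p, miR-193a-3p and miR-219a-5p passed in edgeR over all miRNAs (adjusted p = 0.038, 0.00603 and 0.000163), and 6 astrocyte members over the list alone. Camera with the preset correlation gave adjusted p of 0.212 for the astrocyte, 0.192 for the endothelial and 0.381 for the oligodendrocyte list. With an estimated correlation camera gave an adjusted p of 0.782 for each, and fry gave 0.488, 0.492 and 0.488. With the preset correlation the astrocyte list passed beside the miR-7 family without control 2, and the endothelial list without SCI 2, so that 2 lists passed in each case. Adjusted over the list alone, 0 members of the astrocyte list passed with total count scaling or without control 3, SCI 1 or SCI 3 (6 without control 2), and miR-143-3p did not pass in the endothelial list with total count scaling or when any 1 library other than control 1 was left out. In the oligodendrocyte list miR-219a-5p passed without control 2, without the filter on low counts and in DESeq2, and miR-27a-3p and miR-338-3p without control 1.

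Immune and blood miRNAs went both ways. Of 13 measured microglia, myeloid and inflammation miRNAs 6 were higher and 7 lower (median -0.02, which turned to 0.10 with total count and 0.0038 with upper quartile scaling). miR-342-3p stood at 1597 ± 525 CPM in control and 2763 ± 616 in SCI (0.79 ± 0.24), and miR-155-5p, which activated myeloid cells induce, at 17.2 ± 3.91 and 24.0 ± 4.25 (0.49 ± 0.22). miR-21a-5p, commonly raised in reactive glia, stood at 5320 ± 991 and 5230 ± 253, with a log2 fold change of -0.13 without control 2 and 0.13 without control 1, and miR-22-3p differed by -0.23 ± 0.13 (-0.14 without SCI 3). miR-146a-5p stood at 591 ± 263 and 463 ± 109, with 892 in control 1, and its log2 fold change of -0.35 turned to 0.07 without that library, and was -0.57 without SCI 2, -0.56 without control 2 and -0.23 without SCI 3. Of 11 blood cell miRNAs 7 were higher and 4 lower (median 0.11). The erythrocyte miRNA miR-451a stood at 574 ± 161 and 720 ± 319 (0.33, but 0.05 without SCI 3, 0.15 without control 2, 0.56 without control 1 and 0.65 without SCI 1), the joint count of miR-486a-3p and miR-486b-3p differed by 0.54 ± 0.27, miR-25-3p differed by -0.37 ± 0.15, miR-150-5p by -0.28 ± 0.13 (-0.18 without control 3) and the neutrophil miRNA miR-223-3p by -0.27 ± 0.18 (-0.16 without control 2). No member of either list passed in edgeR, over all miRNAs or over the list alone (smallest adjusted p 0.125 and 0.261), and camera gave 0.742 and 0.953. miR-342-3p passed in the microglia list, adjusted over the list alone, without control 3 or SCI 1, with the most abundant read of each arm alone and in DESeq2. Without the filter on low counts it passed in edgeR over all miRNAs (adjusted p = 7.4e-05), and miR-142a-3p (-0.56 ± 0.39 with the filter, singled out after its values were seen) passed beside it over the list alone.

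Neuronal and plasticity lists had more members lower than higher as well, but more higher than lower with total count scaling. Of 16 neuron-enriched miRNAs 6 were higher and 10 lower (median -0.07, 0.05 with total count scaling), with miR-124-3p, a miRNA largely specific to neurons, at 12802 ± 3288 CPM in control and 16221 ± 1319 in SCI (0.34 ± 0.18, with 0.17 without control 1 and 0.55 without control 3). miR-129-5p differed by -0.41 ± 0.13, miR-221-3p by -0.26 ± 0.12 and miR-139-5p by 0.23 ± 0.11. Of 16 activity-regulated miRNAs 6 were higher and 10 lower (median -0.10, 0.01 with total count scaling). Besides miR-132-3p these include miR-132-5p (-0.27 ± 0.14, and -0.12 without control 1), miR-184-3p (0.46 ± 0.19) and miR-376c-3p (0.31 ± 0.14). Of 20 axon growth and injury-associated miRNAs 9 were higher and 11 lower (median -0.01, 0.11 with total count and 0.02 with upper quartile scaling), among them miR-132-3p, miR-9-5p, miR-155-5p and miR-221-3p. No member of the 3 lists passed in edgeR, with smallest adjusted p over the list alone of 0.164, 0.107 and 0.0939, and camera gave 0.688, 0.953 and 0.953. Without the filter on low counts miR-132-3p passed over the activity-regulated and the axon growth list alone.

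In the choroid plexus and ependyma list 6 of 13 members were higher and 7 lower (median -0.13), with miR-449a-5p, of ciliated cells, at 0.57 ± 0.21. Among the epithelial members, miR-200a-3p stood at 38.7 ± 19.3 CPM in control and 20.95 ± 2.74 in SCI (-0.89 ± 0.31), miR-141-3p at -0.78 ± 0.25 and miR-429-3p at -0.64 ± 0.23. The epithelial miR-200c-3p and miR-200b-3p differed less, by -0.45 ± 0.23 and -0.36 ± 0.20. Control 1 held 60.9 CPM of miR-200a-3p, and without it the values were -0.40 for miR-200a-3p and -0.37 for miR-429-3p. Of 6 muscle miRNAs 5 were higher (median 0.18), with miR-206-3p at 2.42 ± 0.345 CPM in control and 4.59 ± 1.64 in SCI (0.90, and 0.60 without SCI 1), miR-133a-5p at 0.69 ± 0.54 (0.07 without SCI 1, 0.41 without control 1, 1.35 without control 3), miR-499-5p at 0.12 ± 0.16 (0.06 without control 2, 0.20 without control 1) and the joint count of miR-133a-3p and miR-133b-3p at 69.5 ± 13.0 and 75.4 ± 4.94. Of 5 measured miRNAs of posterior or thalamic tissue 3 were lower (median -0.31), among them miR-182-5p (-0.45 ± 0.21, and -0.20 without control 1), miR-183-5p (-0.31 ± 0.25) and miR-10a-5p (-0.52 ± 0.29, and -0.19 without control 2). miR-10b-5p differed by 0.33 ± 0.32, with 0.12 without control 1, 0.17 without SCI 2, 0.21 without SCI 3, 0.58 without SCI 1 and 0.68 without control 3. Of 11 p53- and hypoxia-associated miRNAs 9 were higher (median 0.19), with miR-194-5p at 0.30 ± 0.14, miR-210-3p at 0.19 ± 0.18 (0.06 without control 2, 0.37 without control 1), miR-34c-3p at 0.30 ± 0.38 and miR-34a-5p at -0.09 ± 0.11 (0.0242 with total count scaling, -0.04 without SCI 1). miR-34c-3p turned to -0.0762 without SCI 2 and -0.02 without control 1, and was 0.46 without SCI 3, 0.47 without SCI 1 and 0.74 without control 3. Of 10 let-7 family members 7 were lower (median -0.19), with let-7i-5p at -0.35 ± 0.11, miR-98-5p at -0.33 ± 0.13, let-7f-5p at -0.24 ± 0.11 (-0.16 without control 2) and let-7e-5p at 0.26 ± 0.14 (0.15 without control 1). With total count scaling the medians were -0.03 for the choroid plexus, 0.29 for the muscle and -0.19 for the posterior or thalamic list. They were 0.30 for the p53 and hypoxia list, with all 11 members higher, and -0.07 for let-7. No member of these 5 lists passed in edgeR over the list alone (smallest adjusted p 0.0748, 0.0764, 0.253, 0.611 and 0.134), and camera gave adjusted p of 0.354, 0.354, 0.626, 0.413 and 0.354. miR-206-3p passed, adjusted over the list alone, with total count scaling and without SCI 2, and let-7i-5p without control 1. Without the filter on low counts miR-206-3p, miR-200a-3p and miR-429-3p passed over their lists, and miR-200a-3p over all miRNAs in edgeR (adjusted p = 0.00479).

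The imprinted Dlk1-Dio3 cluster on chromosome 12, a large cluster of miRNAs expressed in the brain, split into 26 members higher and 32 lower of 58 measured (median -0.04, 0.08 with total count scaling). Adjusted over the list alone 2 rose: miR-1197-3p, from 0.923 ± 0.291 to 4.11 ± 1.54 CPM (2.06 ± 0.36, edgeR adjusted p = 0.0148, 5 to 20 counts per control library), and miR-3072-3p (edgeR adjusted p = 0.0466). miR-412-5p stood at 51.9 ± 10.9 and 86.9 ± 20.2 CPM (0.74 ± 0.23), and miR-543-3p was lower without passing. Mir1197 lies at 109712317 to 109712436, Mir543 at 109717258 to 109717333 and Mir3072 at 109747878 to 109747960, all on the plus strand, so miRNAs of opposite direction are neighbours in 1 cluster. Camera gave an adjusted p of 0.953 for the list. miR-1197-3p was the 1 member that passed, adjusted over the list alone, without control 1, control 2, SCI 1 or SCI 3, 0 passed without control 3 or with the filter at 10 CPM, 6 passed without SCI 2, 5 in DESeq2 and 7 without a filter.

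**Figure D4:**
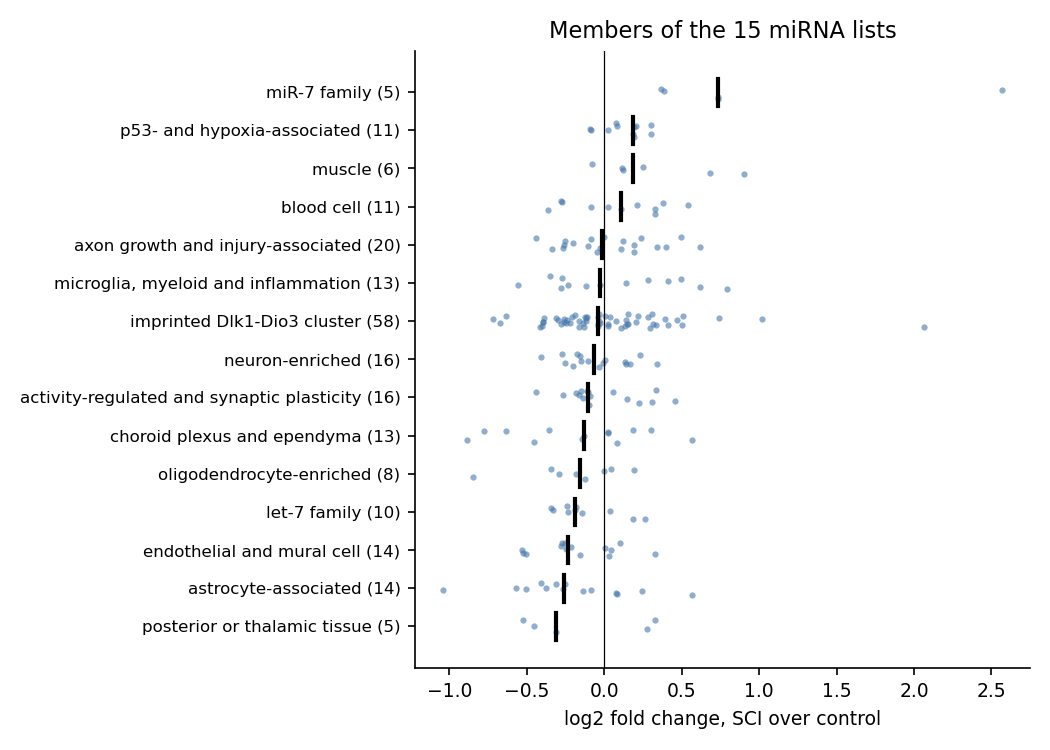
log2 fold change of SCI over control for each tested member (points) of the 15 miRNA lists, with the number of tested members in brackets and the median as a black bar; vertical jitter within a list carries no value. The miR-7 family has the highest median, at 0.73, and the posterior or thalamic list the lowest, at -0.31.

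The balance between the arms of a hairpin was compared next. The log2 ratio of miR-181b-1-3p, from Mir181b-1 (chromosome 1, 137966639 to 137966718), to miR-181b-5p stood at -10.0 ± 0.405 in control and -8.23 ± 0.529 in SCI, a difference of 1.81 ± 0.33, with the 5p arm lower and the 3p arm higher. Reads of miR-181b-5p come from Mir181b-1 and Mir181b-2 alike, so this is not the balance of 1 hairpin, and the ratio of miR-181b-2-3p to the same 5p count differed by 0.21 ± 0.24. The 3p to 5p ratio differed by 1.24 ± 0.24 in Mir5615-1, whose arms share their main reads with Mir5615-2, 1.03 ± 0.22 in Mir345 and 0.73 ± 0.16 in Mir667. Of 278 hairpins tested with limma 0 passed (smallest adjusted p 0.162), with 30 at an unadjusted p under 0.05. The unadjusted count was 19 without SCI 1 and 10 without SCI 3.

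Among single read sequences, ATAATACATGGTTGATCTTT, a read from the 3p arm of Mir369 (chromosome 12, 109743418 to 109743496, plus strand), stood at 77.5 ± 20.2 CPM of all reads in control and 16.7 ± 2.05 in SCI (-2.29 ± 0.25). The main read of that arm, AATAATACATGGTTGATCTTT, is 1 base longer at its 5' end, and miR-369-3p as a whole differed by -0.39 ± 0.12. Reads that start 1 base inside the main 5' end were a smaller share in SCI for 219 of 272 miRNAs with a sharp 5' end. TCCCGGACGAGCCCCCA, which matches the pseudogene Gm15280 and ends in CCA as mature tRNAs do, stood at 82.2 ± 2.94 and 30.9 ± 4.37 (-1.49 ± 0.18). The other named sequences had no match to the annotation: 3 reads of 29 nt stood at 4.87 ± 0.207, 5.18 ± 1.045 and 0.731 ± 0.147 CPM in control and at 22.1 ± 5.51, 23.0 ± 3.10 and 5.29 ± 1.35 in SCI, and 1 of 17 nt at 4.75 ± 0.922 and 0.455 ± 0.0622. edgeR passed 0 of 31242 sequences (adjusted p 0.126 for each of the 6), with 5282 at an unadjusted p under 0.05, and DESeq2 passed 2246, 1638 higher and 608 lower. Without SCI 1 the edgeR count was 3544, of which 3309 were higher.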

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

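The search behind the reads given here was chosen only after the data had been seen. It took reads outside the miRNA hairpins with at least 1000 counts over the 6 libraries and asked for a level at least 10 times that of every control library in each SCI library. Of 2394 such reads, 4 met it, and 0 met it in the other direction. All 4 end in the same bases. That they stood above the control level was required by the search.

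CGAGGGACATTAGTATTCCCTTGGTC, of 26 nt, had a mean of 289.52 CPM of all reads in the SCI libraries (50.4, 265 and 553 in SCI 1, 2 and 3) and 0.922 in the control libraries (5, 14 and 30 counts). It lies on the sense strand of transcripts of B230220B15Rik, Rab3gap1 and Slc38a6, and on either strand in 8 genes. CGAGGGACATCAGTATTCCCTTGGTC, also of 26 nt, had a mean of 227.1 CPM in the SCI libraries (38.0, 206 and 437) and 0.466 in the control libraries. It lies in the sense of 4930430F08Rik and D10Wsu102e, and on either strand in 3 genes. The forms of 24 nt, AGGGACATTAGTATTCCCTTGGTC and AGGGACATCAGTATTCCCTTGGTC, had means of 74.687 and 49.385 CPM in the SCI libraries, with 8.82, 53.5 and 162 for the first and 5.33, 29.3 and 114 for the second. The control libraries held 0 to 2 counts of the first and 0, 0 and 10 of the second. That each was higher in 3 of 3 SCI libraries follows from the search and is no separate result. edgeR gave each an adjusted p of 0.126 among 31242 sequences, so none passed. No explanation was tested for these reads, and which of the genes they come from cannot be read from sequences of this length.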

How the results depend on the processing

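Counting tailed reads, sharing out reads of several arms and leaving out arms found in 10 or more other genes were tests chosen after the result was seen, and the rest were planned. Over the alternatives other than leaving out a library, 816 of 845 values of the named miRNAs kept direction and side of the threshold, 23 passed where they had not before, and 6 reversed. Without single libraries 385 of 396 kept both, 6 passed and 5 reversed. No named miRNA passed over all miRNAs in the main test, so keeping the side of the threshold meant only that it again did not pass. Changes of size were not counted here. Of 88 differences in read share 79 kept their direction. No arm ratio passed in limma under any alternative, with 10 (without SCI 3) to 35 at an unadjusted p under 0.05. Where a cause is not named below, the cause was not tested. How depth limits the calls was not tested.

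With total count scaling 0 lists passed, and the miR-7 family median was 0.85. That scaling turned miR-21a-5p to 0.0965, miR-26a-5p to 0.068 and miR-34a-5p to 0.0242. miR-21a-5p also turned with upper quartile scaling (0.0038), the filter at 10 CPM (0.0139) and tailed reads (0.00247). DESeq2 passed 12 miRNAs and 2246 sequences. Without a filter edgeR passed 30 miRNAs, with 149 at an unadjusted p under 0.05 among more tested, and the filter at 10 CPM left 63 among fewer tested. With each distinct sequence counted once, the share differed by -0.101 points for rRNA, -0.152 for mitochondrial tRNA and -0.529 for mRNA, since abundant reads then carry no extra weight.

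Leaving out each library in turn, edgeR passed 0 to 7 miRNAs (7 without SCI 2, 2 without SCI 1), with 48 (without SCI 3) to 105 (without control 2) at an unadjusted p under 0.05. It passed 0 to 3544 sequences (3544 without SCI 1). Camera passed 0 lists (without control 1, control 3 or SCI 1) to 2 (without control 2 or SCI 2), and the miR-7 family median ran from 0.50 without SCI 1 to 0.97 without SCI 2. miR-146a-5p ran from -0.57 to 0.0737 (without control 1), miR-21a-5p from -0.13 to 0.13 (without control 1) and miR-34c-3p from -0.0762 (without SCI 2) to 0.74. The share differed by -0.135 to 0.0326 points for snoRNA (higher in SCI without control 1 or SCI 1) and by -0.0524 (without control 3) to 0.0133 for other short noncoding RNA (higher in SCI without control 1, control 2, SCI 1 or SCI 3).

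The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at 0.199, -0.055 and -0.074. With the replicate block edgeR passed 0 miRNAs, with 103 at an unadjusted p under 0.05, and 2 sequences, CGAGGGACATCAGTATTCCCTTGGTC and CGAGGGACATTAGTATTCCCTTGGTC (adjusted p = 0.0429 each, named after their values were seen), while 0 lists passed, with a miR-7 family median of 0.67 (camera adjusted p = 0.0689). With the block 0 of the 5 miR-7 members passed, adjusted over the list alone (4 without it), 1 of the astrocyte list (3 without it), 4 of the Dlk1-Dio3 cluster (2 without it) and miR-342-3p of the microglia list.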

Other observations

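The tests given here were chosen only after the result that each addresses was seen. For 1 copied molecule, for fragments of longer transcripts and for minor arms, the bound was written before the deciding value was seen. DESeq2 called 4 miRNAs that the rule for named miRNAs did not take, and they are named here after their values were seen. miR-296-5p, from the imprinted Gnas domain, stood at 92.8 ± 14.0 CPM in control and 148 ± 28.6 in SCI (log2 fold change 0.67 ± 0.19, DESeq2 adjusted p = 0.0474). miR-701-5p stood at 2.02 ± 0.569 and 6.14 ± 1.40 CPM (1.55 ± 0.28, DESeq2 adjusted p = 0.00111). For both, all 3 SCI libraries lay above all control libraries. The other 2, miR-1954/5098-3p (2.42 ± 0.55) and miR-3470a-3p (1.52 ± 0.47), share their main read with 433 and 106 other genes. With the filter on low counts all 4 missed the threshold in edgeR (adjusted p of 0.256, 0.116, 0.157 and 0.256), and without it all 4 passed. With the filter, edgeR also passed miR-701-5p without SCI 2 and miR-1954/5098-3p without SCI 1.

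All 5 members of the miR-7 family were higher in SCI, most of all miR-7b-3p in SCI 1. Tissue of pituitary type in the SCI samples is argued against by miR-375-3p and 5 miRNAs of the miR-200 family, abundant in pituitary. Their median log2 fold change was -0.55 with all 6 lower. miR-375-3p stood at 25.1, 36.3 and 21.2 CPM in control and 20.9, 23.4 and 15.7 in SCI, so the groups overlapped. The other 5 stand in the choroid plexus list too. Without control 1 miR-200a-3p differed by -0.40 and miR-429-3p by -0.37. The bound for this test was set after the data had been seen, so meeting it is no independent support. What argues against such tissue is only that none of these markers rose in SCI. A copied form of the most abundant miR-7b-3p read is argued against as well. That read made up 49.1% of the miR-7b-3p reads in SCI 1, against 80% to 84.4% in the controls. A copied molecule of another sequence or 3' end could not be seen by this test. SCI 1 held 13 distinct sequences and the controls 5 or 6. These numbers decide nothing, since SCI 1 held 1000 such reads and the controls 45 to 141. A general shortening of 3' ends in SCI 1 was not decided. Reads ending early were more frequent than in the controls by a median of 2.01 points over 454 arms. That lies between the bounds of 2 and 10 that were set, just above the lower one. The change was -6.06 for miR-7a-5p, -8.95 for miR-7b-5p and 32.2 for miR-7b-3p, which lay above 99.78% of the arms. The arm counts take reads of any 3' end from 18 to 26 nt, so shortening adds no reads within that range. An effect of the injury stays open and was not separated from other differences between the libraries.

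Reads starting 1 base inside the main 5' end were a smaller share in SCI, with a median log2 difference of -0.27 over 272 miRNAs (library medians -6.37, -6.32 and -6.49 in control, -6.76, -6.77 and -6.87 in SCI, two-sided exact permutation p = 0.1, the smallest 3 against 3 can give). Other RNA with a sharp 5' end had a median of -0.22 over 28 start sites (20 lower, exact permutation p = 0.1), and reads without a match -0.21 over 75. Base loss at 5' ends that differs between libraries is a candidate explanation. The pooled value of -0.22 lay just under the bound of -0.2. That bound was written after the data had been seen, so meeting it is no independent support. By class, mitochondrial tRNA stood at -0.43 over 7 sites, mRNA or long noncoding RNA at -0.32 over 5, snoRNA at -0.28 over 6 and rRNA at -0.12 over 4. Other short noncoding RNA at 0.15 and predicted miRNA-type hairpins at 0.27, over 3 sites each, went the other way. For a change in miRNA cleavage alone, the bound set against it, also written after the data had been seen, was met. Other RNA lay under -0.2, and its SCI library medians (-5.59, -5.94 and -5.69) all lay below those of the controls (-5.36, -5.10 and -5.55). A change in cleavage alone still stays open. The 95% bootstrap interval of the median over the 28 start sites of other RNA, from -0.49 to -0.056 in 10000 draws, reaches above -0.1. That interval describes the spread between start sites and not the spread between libraries. Some classes of other RNA also went the other way, as given above. Whether the injury changes either was not tested.

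The 8 miRNA arms whose main read occurs in 10 or more other genes were all higher in SCI (median log2 fold change 1.25), 3 of them with all SCI libraries above all controls, as for miR-1954/5098-3p. miR-3470a-3p stood at 11.3, 38.8 and 21.8 CPM in SCI 1, 2 and 3 and up to 11.8 in control, and miR-3470b-3p at 17.6, 69.6 and 36.0 and up to 22.7, where reads of 30 to 34 nt took 0.584%, 3.66% and 2.31% of SCI 1, 2 and 3; control 1, with 1.33% of such reads, held 4.21 and 8.36 CPM of the pair, the lowest of the 6 libraries. Of the reads in their hairpins 23.1% were 20 to 24 nt long (3.02% to 66.7% by arm), against 95.3% of all hairpin reads. Fragments of longer, repeat-bearing transcripts are thus a candidate explanation of what these reads are, as under 80% was needed. The share pools all 6 libraries, so it does not tell why the arms were higher in SCI. Of the arms, miR-1187-5p, miR-3470b-5p and the joint count of miR-3473b and miR-3473e were scarce, with at most 1.34, 1.47 and 2.11 CPM in any library. The values of control 1 and SCI 1 do not follow the share of long reads, and a larger amount of repeat transcripts after the injury stays open and untested.

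Since several of the miRNAs of smallest p that were higher in SCI are minor arms, the minor arms were asked to make up a larger share as a class. This hypothesis was negative: over 246 hairpins the median log2 ratio of minor to major arm differed by 0.00735 (two-sided exact permutation p = 0.7), and it was higher in SCI in 114. The 6 libraries can be split 3 against 3 in 10 ways, which are too few for a share under 0.05. The real split gave 97 miRNAs at an unadjusted p under 0.05 in edgeR and the highest other 71 (1 of the 10 as large), and 30 hairpins at an unadjusted p under 0.05 in limma against 21 (1 of the 10 as large). It passed 1 list in camera, and the highest other passed 4 (7 of the 10 as large), in the split that sets control 1, control 3 and SCI 2 against the rest. The miR-7 family passed there, in the real split, and in the split that sets control 1, control 2 and SCI 2 against the rest. A structure of the samples beside their groups was not tested. For sequences the edgeR count was 0 in the real split, with 5282 at an unadjusted p under 0.05 and 2246 passed by DESeq2, and 0 in all others, so that 10 of the 10 are as large by construction and the comparison carries no information.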
